A study of Mus musculus with 12 samples.

How the data were processed

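RNA was measured by stranded mRNA sequencing in HC11 cells, a mouse mammary epithelial line. The cells carried a control construct or a knockdown of Snail1, the protein encoded by Snai1. Per the labels, sorted cells were left to aggregate overnight and entered an in vitro collective migration assay, and RNA was taken at 0 h and 36 h. The 12 libraries form 4 groups of 3: control at 0 h (libraries 1, 2 and 3), control at 36 h (libraries 1, 3 and 4), knockdown at 0 h (libraries 1, 2 and 3) and knockdown at 36 h (libraries 1, 2 and 3). Groups were taken from the sample titles. The title of control 36 h library 4 begins with "mix", which the labels do not explain, and it was kept in its group. If it is a pool of other libraries, control at 36 h holds 2 independent samples, and n = 3 and the p-values of that group overstate the replication. The labels do not say that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples.

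The submitters' processing notes name FastQC, cutadapt 1.9.1, HISAT2 2.2.1, HTSeq and DESeq2 and the mouse build GRCm39, without saying which program did what. Which of them made the values is not stated. The deposited table holds gene-level TPM (transcript abundance scaled for gene length and library total) from the authors for 57180 genes in each library, on a scale where every library has the same total. The authors also gave a gene length in bases and group means in TPM. Recomputed within 1e-04 TPM, the means cover all 3 libraries in 3 groups, but the control 36 h mean covers only libraries 1 and 3, and 1 further column repeats control 36 h library 4 alone. These columns were not used as measurements. Read counts were not recovered from the TPM, so the depth of each library is unknown, no counting error can be given, and models for counts were not used. No genomic coordinates were used, because the annotation at hand is for another build than the one named.

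Genes with at least 1 TPM in at least 3 of the 12 libraries were tested (14426 genes). A value of 1 was added to the TPM before taking log2, so log2 fold changes are on the log2(TPM + 1) scale, which understates changes of genes with low levels. All 12 libraries were fitted in one model with one mean per group in limma 3.58.1 (lmFit, contrasts.fit and eBayes with a trend in the variance) under R 4.3.3. The 5 comparisons were knockdown minus control at 0 h and at 36 h, 36 h minus 0 h in control and in knockdown, and the difference between those last changes. P-values are two-sided and were adjusted by Benjamini-Hochberg over all genes tested in each comparison, and a gene was called at an adjusted p under 0.05. Snai1 was also tested by an exact two-sided permutation test within each pair of groups, which cannot go below 0.1 with 3 libraries against 3.

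30 gene lists were written from textbook knowledge of migrating mammary epithelium, together with the model, the comparisons, the settings to vary and the rule for naming genes, before the data were examined. Each list was tested with limma's camera at a preset correlation between genes of 0.01, and again with a correlation estimated from the data. P-values of the lists were adjusted over the 30 lists of a comparison. Camera compares a list with the other tested genes, so its direction is relative to them. Members that pass were counted over all genes tested and also adjusted over the list alone. Some genes stand on more than one list. The list of unfolded protein and amino acid stress genes holds 26 symbols and 27 measured genes, because Ddit3 stands for more than one identifier.

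The genes named by rule were Snai1, then the 5 largest rises and 5 largest falls among called genes with a mean of at least 5 TPM in the higher group and no overlap between the libraries of the groups (predicted genes, pseudogenes and genes without a symbol were left out), then up to 4 called members with the lowest adjusted p of each list that passed camera or held at least 5 called members, and 8 markers, namely Cdh1, Vim, Fn1, Cdh2, Snai2, Zeb1, Krt8 and Krt14. The rule gave 94 called genes for the knockdown at 0 h, 32 at 36 h, 19 over time in control and 33 over time in knockdown, and the text takes its examples from them. Zeb1 was below the filter and was not tested.

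The alternatives were a pseudocount of 0.1, no filter, a filter of 5 TPM, median-of-ratios scaling, quantile normalization, removal of mitochondrial genes, a robust variance, no variance trend, a minimum fold change of 2, the replicate number as a block (alone and with median-of-ratios scaling), fits of only the groups compared, and leaving out each library in turn. Array weights, leaving out knockdown 0 h library 2 together with control 36 h library 4, and leaving out knockdown 0 h library 2 with median-of-ratios scaling were added after seeing the data. KEGG pathways from the deposited annotation with 10 to 300 tested genes and a list of 22 NRF2 target genes were also added then. The NRF2 list held only genes whose values had not yet been looked at. The model was tested on simulated data with 14426 genes at the observed spreads, of which 100 changed by 2-fold and 100 by 4-fold. At an adjusted p under 0.05 it recovered 22% of the 2-fold and 63% of the 4-fold changes for the knockdown at 0 h, and 25% and 74% at 36 h. For the difference of the 36 h changes it recovered 1% and 45%, with 3 to 9 false calls over the 5 comparisons. A simulation without knockdown 0 h library 2, added after seeing the data, recovered 29% and 75% for that difference. The simulated noise was independent between genes and gave a gene the same spread in all groups. These rates need not hold where many more genes change, or where the libraries of 1 group spread more. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.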

Results

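RNA levels were measured in aggregates of HC11 mouse mammary epithelial cells, with a control construct or a knockdown of Snail1, before (0 h) and after (36 h) an in vitro migration assay. Each of the 4 groups held 3 libraries, and 14426 genes were tested. The series addresses the role of Snail1, a transcriptional repressor tied to the epithelial-mesenchymal transition, in collective migration. Values are TPM as mean ± SD over the 3 libraries of a group, changes are log2 fold changes on the log2(TPM + 1) scale with their standard error (SE), and the depth of the libraries is unknown. Between 12957 and 13945 genes reached 1 TPM in a library.

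The control libraries lay together on the second principal component of expression, and 2 knockdown libraries at 0 h stood apart. On the first component control 36 h library 3 (-7) lay nearer to the knockdown libraries at 36 h (-5.5 to 9.7) than the other 5 control libraries did (-47.5 to -29.5). In knockdown 0 h library 2, mitochondrially encoded genes took 13.99% of the TPM, against 1.45% to 6.15% in the other 11 libraries. Ribosomal protein genes took 13.45% there, against 4.34% to 6.57%, and genes shorter than 300 bases took 10.55%, against 2.32% to 5.23%. Its median correlation with the libraries of its group, across genes, was 0.862, against 0.894 to 0.970 in the other 11. Its median-of-ratios scaling factor was 0.504, against 0.897 to 1.22. In knockdown 0 h library 3, 27715 genes had a TPM above 0, against 20932 to 23427 in the other 11, its second component was the lowest (-50.6), and its correlation with its group (0.894) was the lowest after that of library 2. Both libraries were kept, and the counts of genes that move without them are given.

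**Figure D1:**
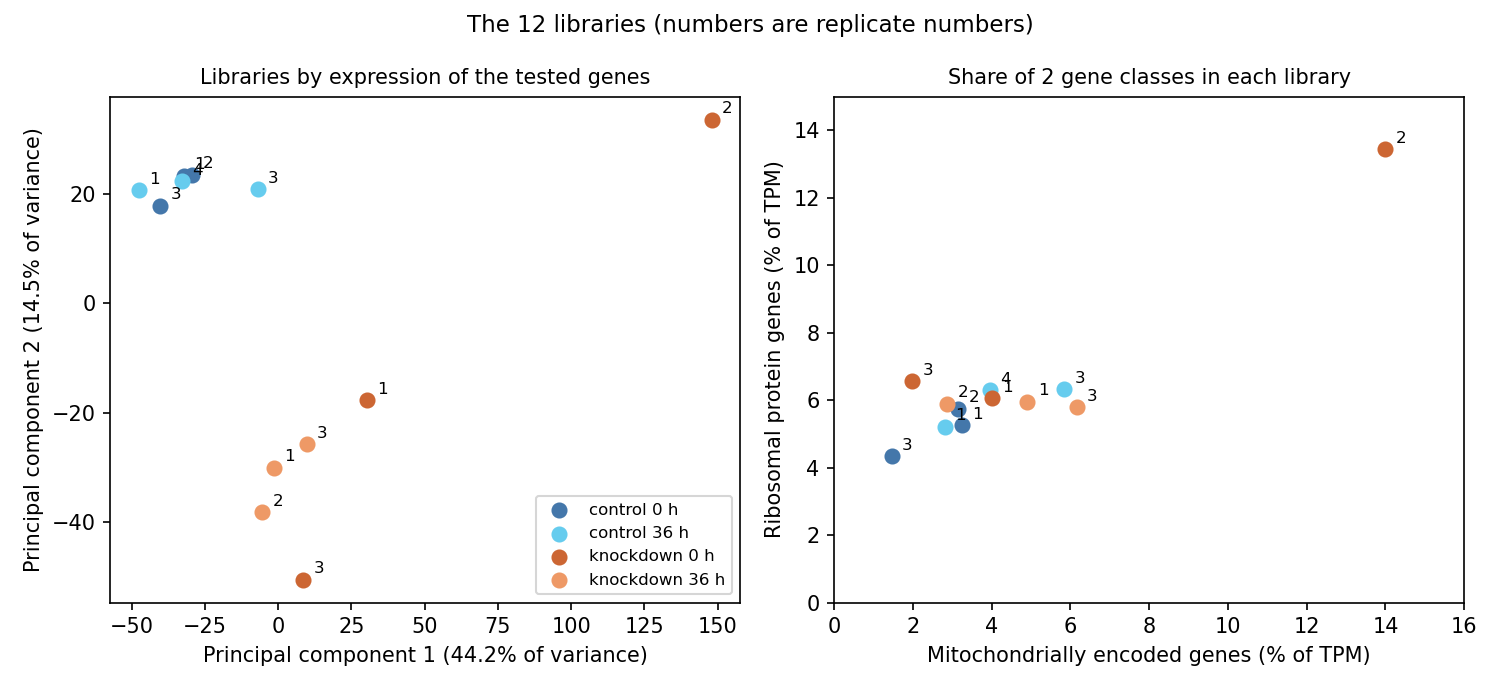
Left, the first against the second principal component (44.2% and 14.5% of the variance) of the tested genes in the 12 libraries, as component scores; right, the share of mitochondrially encoded against ribosomal protein genes, as percent of TPM. Each point is a library with its replicate number, colored by group, and knockdown 0 h library 2 stands at 13.99% and 13.45%.

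Snai1 (ENSMUSG00000042821), the targeted gene, was lower in the knockdown at both times. At 0 h it stood at 0.617 ± 0.158 TPM in the knockdown and 1.85 ± 0.601 TPM in control (n = 3 each), which is 33.4% of control, a log2 fold change of -0.80 (SE 0.227, adjusted p = 0.0348). At 36 h it stood at 0.407 ± 0.192 TPM and 3.13 ± 0.688 TPM, which is 13.0% of control, a change of -1.55 (SE 0.227, adjusted p = 0.0106). All 3 knockdown libraries lay below all 3 control libraries at each time, and the exact permutation p was 0.1, the smallest that 3 against 3 allows. Between 0 h and 36 h Snai1 changed by 0.54 in control (adjusted p = 0.772) and by -0.21 in the knockdown (adjusted p = 0.559), and neither passed, nor did their difference of -0.75 (adjusted p = 0.595). The 0 h call was lost without control 0 h library 1 (adjusted p = 0.0590), 2 (0.122) or 3 (0.0828), knockdown 0 h library 1 (0.0576) or knockdown 36 h library 2 (0.0525), and with median-of-ratios scaling (-0.51, adjusted p = 0.191). The 36 h call was lost without control 36 h library 4 (0.0695) or knockdown 36 h library 2 (0.0576) or 3 (0.0615).

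Among markers of epithelial and mesenchymal state, the mesenchymal genes Fn1 (ENSMUSG00000026193, fibronectin) and Vim (ENSMUSG00000026728, vimentin) were lower in the knockdown. Fn1 stood at 33.6 ± 5.74 TPM against 122 ± 21.4 TPM at 0 h (-1.83, SE 0.358, adjusted p = 0.00864) and at 20.3 ± 5.79 TPM against 85.4 ± 38.1 TPM at 36 h (-1.94, SE 0.358, adjusted p = 0.0230). Vim stood at 13.7 ± 3.17 TPM against 30.3 ± 6.39 TPM at 0 h (-1.09, SE 0.224, adjusted p = 0.0108) and at 25.8 ± 3.30 TPM against 55.6 ± 3.60 TPM at 36 h (-1.08, SE 0.224, adjusted p = 0.0334). With median-of-ratios scaling the 0 h change of Vim was -0.60 (adjusted p = 0.0725), and without control 0 h library 1 it was -0.94 (0.0553). At 36 h Vim lost its call in 11 of 26 alternatives (largest adjusted p = 0.363), among them the fits without control 0 h library 1 or 2 or any library of the 36 h groups. Fn1 lost it at 36 h in 8 of 26 (largest 0.235), among them the fits without control 36 h library 1 or 4 or any knockdown 36 h library, and at 0 h in 1 of 26 (0.0630). Cdh1 (ENSMUSG00000000303, E-cadherin) had values of -1.0 at 0 h (adjusted p = 0.150) and -0.24 at 36 h (adjusted p = 0.888), and neither passed. Krt8 and Krt14, keratins of luminal and basal cells, had -0.79 (adjusted p = 0.153) and -0.51 (adjusted p = 0.331) at 0 h, and 0.06 (0.974) and 0.48 (0.626) at 36 h. Snai2, a relative of Snai1, had -1.13 at 0 h (adjusted p = 0.0518) and -0.51 at 36 h (adjusted p = 0.571), and Cdh2 (N-cadherin) had -0.59 (0.260) and -0.21 (0.873). None of these passed, but all 3 knockdown libraries lay below all 3 control libraries for Snai2 at each time. At 36 h Snai2 stood at 98.1 ± 7.07 against 140 ± 8.53 TPM. Its SE of 0.362 is shared with the knockdown at 0 h (66.3 ± 34.6 TPM). For Krt14 at 36 h all 3 knockdown libraries lay above all 3 control libraries. Zeb1 (ENSMUSG00000024238) was below the filter, with means of 0.473 TPM in control and 0.0833 TPM in the knockdown at 0 h, and 0.403 and 0.120 TPM at 36 h.

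**Figure D2:**
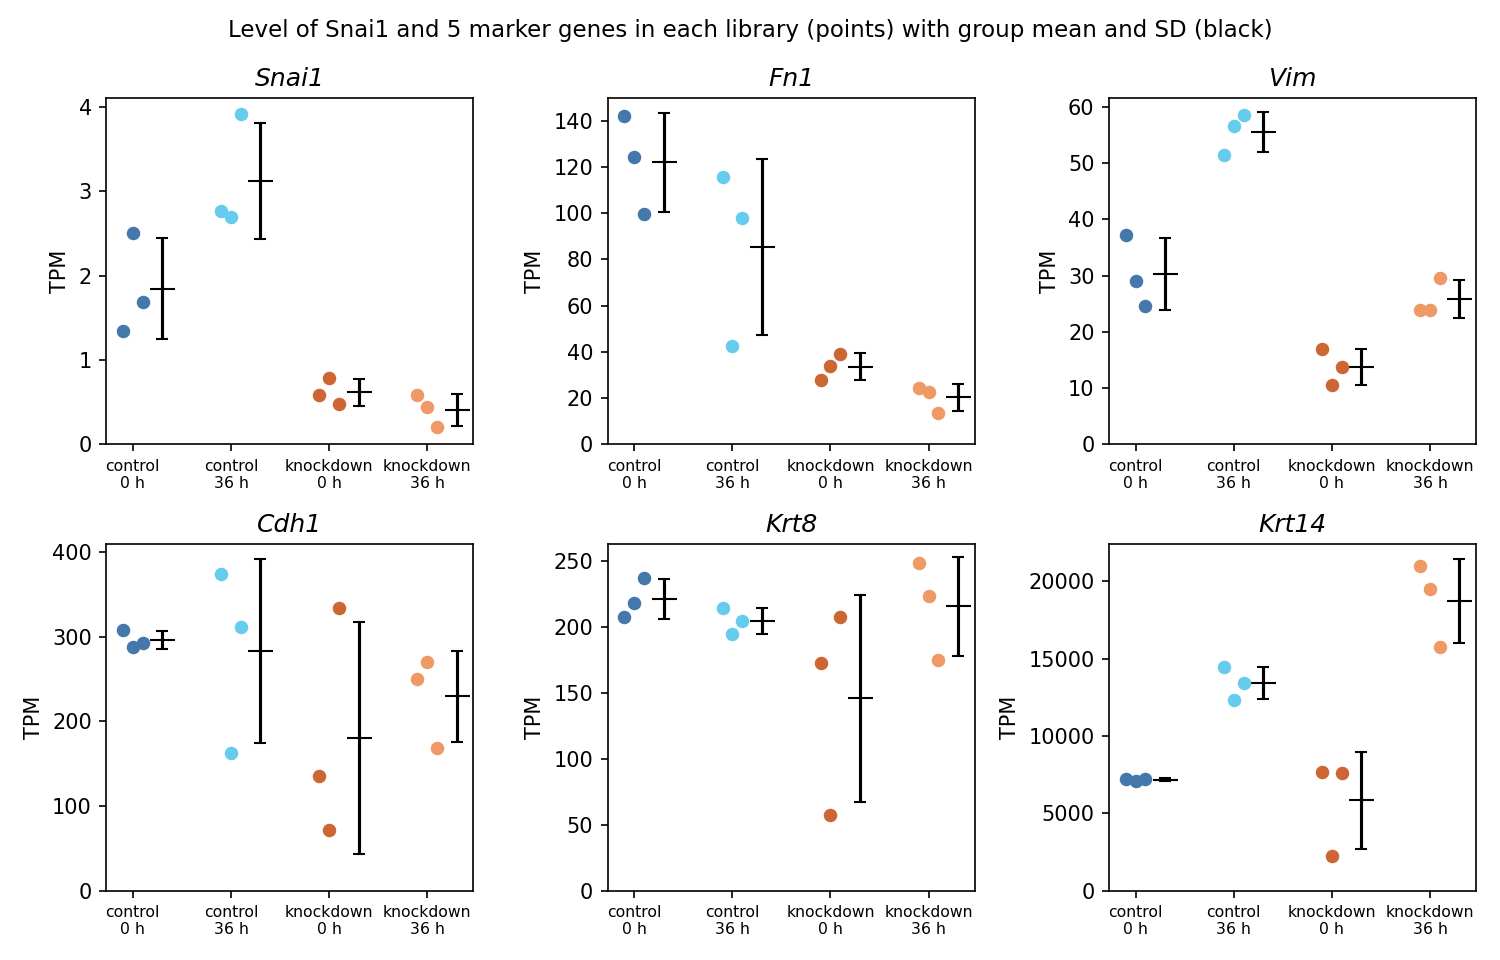
TPM of Snai1, Fn1, Vim, Cdh1, Krt8 and Krt14 (vertical axes) in the 12 libraries by group (horizontal axes), with points for libraries and bars for the group mean ± SD. All 3 knockdown libraries lie below all 3 control libraries at each time for Snai1, Fn1 and Vim, and Cdh1 in the knockdown at 0 h spreads around 180 ± 137 TPM.

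Among the genes called lower in the knockdown at 0 h were 13 of 25 matrix proteases and inhibitors, 14 of 28 integrins and focal adhesion genes and 30 of 30 G2/M phase genes. Of 30 interferon-stimulated genes 5 were higher, and without scaling none of these lists passed camera with an estimated correlation. Among all 14426 genes tested, 2103 were called lower and 447 higher. The matrix metalloproteases Mmp3 and Mmp12 fell from 32.9 ± 18.1 and 78.2 ± 19.9 TPM in control to 1.62 ± 1.66 and 7.60 ± 6.52 TPM (n = 3 each; -3.80, SE 0.509, adjusted p = 0.00183, and -3.52, SE 0.518, adjusted p = 0.00263). Sfrp1 (ENSMUSG00000031548), a secreted modulator of Wnt signaling, fell from 96.5 ± 7.45 to 9.78 ± 4.22 TPM (-3.27, SE 0.299, adjusted p = 4.75e-04), and Angptl2 and Padi4 had -2.98 and -2.96. Among the rises were S100g, a calcium-binding protein (14.6 ± 12.8 against 0.560 ± 0.400 TPM, 3.02, adjusted p = 0.00336), and B2m, part of the MHC class I molecule (1624 ± 247 against 622 ± 30.1 TPM, 1.37, adjusted p = 0.00177). H2ac19 (3.67), Ndufb4b (2.76), Mir678 and Rn7s6 also rose, but they are short or have near-copies, so their levels are uncertain, and Mir678 and Rn7s6 were listed at 0 in control at 0 h. Ndufb4b lost its call in 20 of 26 alternatives, 10 of them with 1 library left out, Rn7s6 in 14 of 25, 9 of them with 1 left out, H2ac19 in 6 of 26 and Mir678 in 4 of 26.

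In all, 2550 genes passed in limma, 447 up and 2103 down (17.5% up). The median of all genes was -0.41, and 0.02 with median-of-ratios scaling, which gave 2718 genes, 1249 up and 1469 down (46.0% up), so the changes at 0 h are relative to that shift. Without knockdown 0 h library 2 there were 3369 genes, 973 up and 2396 down (28.9% up), and 2243 of the 2550 were among them. The count was 755, 1011 and 934 without control 0 h libraries 1, 2 and 3 and 5869 without knockdown 0 h library 3. Of the 94 genes named by rule, 2 kept their call with only the groups compared, 56 without control 0 h library 1 and 81 with median-of-ratios scaling, and 41 lost it in at least 1 fit without 1 library.

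By gene list, 16 of 30 lists passed camera, of which 15 are described, and none passed with an estimated correlation. With median-of-ratios scaling, 3 lists passed with an estimated correlation. The members called down moved with 1 library left out. They ranged from 29 to 30 for G2/M, 8 to 27 for S phase, 8 to 17 for protease and 2 to 19 for integrin and focal adhesion genes. For junction genes they ranged from 1 to 17, for basal genes from 1 to 13 and for mesenchymal genes from 3 to 11. G2/M phase genes, which drive mitosis, had 30 of 30 members down (30 adjusted over the list alone), a median of -2.15 and -1.71 with median-of-ratios scaling (camera adjusted p = 2.12e-19, adjusted p = 0.637 with an estimated correlation). Kif2c, a mitotic motor protein, had -2.47, and Cenpe and Cenpf had -2.11 and -2.31. S phase genes had 22 of 32 down (25 adjusted over the list alone), a median of -1.38 and -0.93 with scaling (5.68e-07, adjusted p = 0.637 with an estimated correlation). Among them were Mcm5, of the DNA replication helicase, at -2.22 and Cdt1 at -1.60. Matrix proteases and inhibitors had 13 of 25 down (15 adjusted over the list alone), a median of -1.09 and -0.71 with scaling (1.05e-04, adjusted p = 0.637 with an estimated correlation). Among them were Plau (urokinase) at -1.69 and Timp3 at -1.63.

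Integrins and focal adhesion genes had 14 of 28 down (16 adjusted over the list alone), a median of -1.04 and -0.65 with scaling (camera adjusted p = 0.00199, adjusted p = 0.704 with an estimated correlation). Among them were Itgb3 at -2.74 and the adaptor Pxn (paxillin) at -2.09. Epithelial junction genes had 12 of 30 down (15 adjusted over the list alone), a median of -0.80 and -0.34 with scaling (0.0259, adjusted p = 0.787 with an estimated correlation). Among them were F11r at -2.18 and Jup (plakoglobin) at -1.45, and the list did not pass without knockdown 0 h library 1 (adjusted p = 0.0521). Basal mammary genes had 6 of 19 down (13 adjusted over the list alone), a median of -1.01 and -0.50 with scaling (0.00944, adjusted p = 0.704 with an estimated correlation). Among them were Cdh3 (P-cadherin) at -1.62 and Igfbp3 at -1.40. Mesenchymal genes had 8 of 17 down (9 adjusted over the list alone), a median of -0.89 and -0.37 with scaling (0.0478, adjusted p = 0.637 with an estimated correlation). Among them were Tgfbi at -1.54 and Sparc at -1.31. The mesenchymal list did not pass without control 0 h library 1 (adjusted p = 0.0629), knockdown 0 h library 1 (0.10) or 3 (0.0943), or knockdown 36 h library 1 (0.050) or 2 (0.0526).

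Of the lists of signaling targets, those of ERK, TGF-beta and p53 passed as lower, and those of YAP, Wnt and Notch, and NF-kB did not pass. ERK pathway target genes had 11 of 22 down (14 adjusted over the list alone), a median of -1.02 and -0.60 with scaling (camera adjusted p = 3.84e-04, adjusted p = 0.637 with an estimated correlation). Among them were Fos at -2.42 and cyclin D1 (Ccnd1) at -1.58. Early response and heat shock genes had 11 of 23 down (18 adjusted over the list alone), a median of -1.12 and -0.63 with scaling (1.98e-04, adjusted p = 0.637 with an estimated correlation). Among them were Jun at -2.42 and the phosphatase Dusp1 at -2.62. TGF-beta target genes had 10 of 21 down (14 adjusted over the list alone), a median of -0.90 and -0.38 with scaling (0.00171, adjusted p = 0.637 with an estimated correlation). Among them were Tgfb3 at -2.48 and Bambi at -1.26. Cholesterol synthesis genes had 10 of 23 down (14 adjusted over the list alone), a median of -0.99 and -0.48 with scaling (0.00127, adjusted p = 0.704 with an estimated correlation). Among them was Sqle, a sterol synthesis enzyme, at -1.84. p53 target genes had 9 of 20 down (12 adjusted over the list alone), a median of -0.92 and -0.47 with scaling (0.0175, adjusted p = 0.704 with an estimated correlation). Among them were Plk2 at -2.39 and Cdkn1a (p21) at -1.26, which did not pass with median-of-ratios scaling (-0.75, adjusted p = 0.0774).

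The lists that were higher were interferon-stimulated, mitochondrially encoded and ribosomal protein genes. Interferon-stimulated genes had 5 of 30 up (5 adjusted over the list alone), a median of 0.70 and 1.13 with scaling (camera adjusted p = 2.45e-07, adjusted p = 0.637 with an estimated correlation). Leaving out 1 library gave medians from 0.16, with 4 called down, without knockdown 0 h library 3 to 1.00 without library 2. Among them were Bst2 (tetherin) at 1.82 and the immunoproteasome subunit Psmb9 at 1.09. Mitochondrially encoded genes had 0 of 15 past the limma threshold, a median of 0.95 and 1.47 with scaling (6.92e-05, adjusted p = 0.637 with an estimated correlation), and 0.22 without knockdown 0 h library 2, where the list did not pass (adjusted p = 0.105). Ribosomal protein genes had 4 of 36 up (0 adjusted over the list alone), a median of 0.58 and 1.10 with scaling (2.36e-14, adjusted p = 0.637 with an estimated correlation), and 0.25 without that library, with Rps14 at 0.69 and Rpl22 at 1.31.

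Without knockdown 0 h library 2 the medians were -0.50 for mesenchymal, -0.51 for junction, -0.60 for basal, -0.57 for TGF-beta target, -0.59 for cholesterol and -0.71 for early response genes. Without library 3 of that group they were -1.53 for basal and 1.66 for mitochondrially encoded genes, and without control 0 h library 3 the mitochondrial median was 0.55. The other 14 lists did not pass camera at 0 h. Of their members, EMT transcription factors had 1 up and 3 down of 9 (1 and 4 adjusted over the list alone), luminal mammary genes 6 of 16 down (10 alone), milk and secretory genes 3 of 9 down (4 alone), and stratified squamous genes 1 up and 7 down of 14 (2 and 8 alone). Elf3, a luminal transcription factor, had -1.53, and Sprr1b and Krt16, cornified envelope and stress keratin genes, had -2.05 and -1.47. Basement membrane genes had 2 of 15 down (4 alone), apicobasal and planar polarity genes 5 of 24 down (5 alone; Pals1 -1.43, Vangl1 -1.59), YAP target genes 1 up and 6 down of 22 (1 and 8 alone), and Wnt and Notch target genes 1 up and 4 down of 16 (1 and 10 alone). NF-kB and chemokine genes had 3 up and 4 down of 23 (3 and 6 alone), with the chemokine Ccl5 at 2.31 and Il6 at 1.12 up and Tnfaip2 at -2.50 down, and their median was -0.63 although camera placed the list above the other genes. Hypoxia and glycolysis genes had 4 of 27 down (7 alone), unfolded protein and amino acid stress genes 1 up and 7 down of 27 (1 and 10 alone; Slc7a11 1.57, Atf3 -2.62), and fibroblast markers 2 of 5 down (2 alone). Immune cell markers had 0 of 3 past the threshold, with a summed level of 12.05 ± 3.29 TPM against 15.52 ± 2.77 TPM in control, and endothelial and adipocyte markers had 0 of 2. The median of immune cell markers (-0.28) and that of endothelial and adipocyte markers (-0.09) were negative while camera placed both lists above the other genes, and the medians of these lists and of YAP target genes changed sign with median-of-ratios scaling.

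At 36 h Chi3l1 (ENSMUSG00000064246), a secreted chitinase-like protein, rose from 118 ± 10.5 TPM in control to 1270 ± 45.5 TPM in the knockdown (n = 3 each; 3.42, SE 0.260, adjusted p = 2.36e-04). The detoxifying enzymes Aldh3a1 (2269 ± 242 against 399 ± 38.2 TPM, 2.51, adjusted p = 0.00446) and Gsta1 (136 ± 22.0 against 24.1 ± 3.18 TPM, 2.44, adjusted p = 0.00954) rose, as did the carboxylesterase Ces1f (2.39, adjusted p = 0.0178) and AW011738 (2.48). Sfrp1 fell again, from 63.5 ± 10.5 to 8.30 ± 1.45 TPM (-2.79, SE 0.299, adjusted p = 0.00276). Plet1 (-2.35), Lipk (-2.37), Orm1 (-2.13) and Itgb3 (-2.24, adjusted p = 0.0246) fell too. Like Sfrp1 and Itgb3, some of these were also called at 0 h. There Chi3l1 (2.37, adjusted p = 9.5e-04) and Gsta1 (2.13, adjusted p = 0.00416) were up, and Plet1 (-2.58) and Orm1 (-2.20) were down.

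In all, 365 genes passed in limma at 36 h, 129 up and 236 down (35.3% up), and the median of all genes was -0.09. Median-of-ratios scaling gave 856 genes and the omission of knockdown 0 h library 2, which takes part in the shared estimate of the spread, gave 2699, of which 998 were up and 1701 down. Of the 365, 364 were among the 2699. The count was 137, 134 and 223 without control 0 h libraries 1, 2 and 3, and 31, 218 and 24 without control 36 h libraries 1, 3 and 4. It was 552 without knockdown 0 h library 3 and 54, 29 and 32 without knockdown 36 h libraries 1, 2 and 3. Of the 32 called genes named by rule, 1 kept its call with the replicate block, and 5 kept their call without control 36 h library 4. In at least 1 fit without 1 library 27 of the 32 lost it, and over all alternatives Cdt1 lost it in 14 of 26, Col3a1 in 14 of 24 and Pxn in 13 of 26.

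By gene list, 13 of 30 passed camera at 36 h, of which 12 are described, and none passed with an estimated correlation. With median-of-ratios scaling, 8 lists passed with an estimated correlation. The counts of called members depended strongly on single libraries. With 1 left out, 0 to 28 G2/M, 0 to 19 S phase, 0 to 13 cholesterol synthesis and 0 to 9 mesenchymal genes were down. For interferon-stimulated genes 0 to 10 were up. Interferon-stimulated genes had 3 of 30 up (15 adjusted over the list alone) and 30 of 30 with a positive value, a median of 0.96 (camera adjusted p = 4.08e-14, adjusted p = 0.733 with an estimated correlation). Among them were Bst2 at 1.48, Psmb9 at 1.45 and B2m at 1.15, which did not pass with median-of-ratios scaling (1.26, adjusted p = 0.0534). The summed level of immune cell markers was 5.23 ± 0.241 TPM against 5.28 ± 0.599 TPM in control. G2/M phase genes had 6 of 30 down (21 adjusted over the list alone), a median of -0.89 (4.08e-14, adjusted p = 0.733 with an estimated correlation). Among them were the proliferation marker Mki67 at -1.86 (2.36 ± 0.673 against 11.3 ± 2.93 TPM, adjusted p = 0.0108) and Top2a at -1.08. S phase genes had 2 of 32 down (7 adjusted over the list alone), a median of -0.77 (1.98e-07, adjusted p = 0.733 with an estimated correlation). Among them were Cdt1 at -0.92 and the nuclease Exo1 at -1.34, which did not pass with median-of-ratios scaling (adjusted p = 0.0661). Cholesterol synthesis genes had 1 of 23 down (5 adjusted over the list alone), a median of -0.56 (5.69e-05, adjusted p = 0.762 with an estimated correlation).

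Mesenchymal genes had 5 of 17 down (1 up and 7 down adjusted over the list alone), a median of -0.76 (camera adjusted p = 2.08e-04, adjusted p = 0.733 with an estimated correlation). Among them were Fn1, Vim, Tgfbi (-1.34) and the collagen Col3a1 (-0.99, adjusted p = 0.113 with median-of-ratios scaling). Integrins and focal adhesion genes had Itgb3 and Pxn (-1.50) down of 28 (4 adjusted over the list alone), a median of -0.71 (2.31e-05, adjusted p = 0.733 with an estimated correlation). YAP target genes had Asap1 (-1.25) down of 22 (6 adjusted over the list alone), a median of -0.59 (0.00188, adjusted p = 0.733 with an estimated correlation). TGF-beta target genes had 2 up, Id2 (1.10) and Id1 (0.85), which inhibit helix-loop-helix transcription factors, and 2 down, Bambi (-1.11) and Tgfbi, of 21 (2 and 4 adjusted over the list alone), with a median of -0.55 (0.0111, adjusted p = 0.763 with an estimated correlation). Early response and heat shock genes had Dusp1 (-1.50) down of 23 (1 adjusted over the list alone, median -0.42, 0.00240, adjusted p = 0.763 with an estimated correlation). Matrix proteases and inhibitors had Serpinb2 (-0.98) down of 25 (5 adjusted over the list alone, median -0.34, 0.0365, adjusted p = 0.863 with an estimated correlation). No member passed in limma among 22 ERK pathway target genes (2 down alone, median -0.47, 0.0153, adjusted p = 0.762 with an estimated correlation) and 15 basement membrane genes (1 down alone, median -0.46, 0.0162, adjusted p = 0.762 with an estimated correlation). Basement membrane genes did not pass camera without control 36 h library 1 (median -0.24, 0.0911; -0.89 without library 3, where they passed), knockdown 0 h library 2 (0.0820) or knockdown 36 h library 3 (0.0527), and matrix proteases did not pass without control 36 h library 1 (0.0830), knockdown 0 h library 2 (0.102) or knockdown 36 h library 2 (0.0636).

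The other 17 lists did not pass camera at 36 h, and their members past the threshold were few. NF-kB and chemokine genes had 2 up of 23 (5 adjusted over the list alone), p53 target genes 2 down of 20 (2 alone), luminal mammary genes 1 down of 16 (2 alone), stratified squamous genes 1 up of 14 (2 up and 2 down alone), milk and secretory genes 1 up of 9 (1 alone), Wnt and Notch target genes 1 up of 16 (1 alone), EMT transcription factors 1 down of 9 (1 alone), hypoxia and glycolysis genes 1 down of 27 (1 alone) and fibroblast markers 1 down of 5 (2 alone). Junction, basal, polarity, unfolded protein, immune, endothelial and adipocyte, mitochondrially encoded and ribosomal protein genes had 0 past the limma threshold (1 up adjusted over the list alone among unfolded protein genes). With 1 library left out, up to 8 junction genes were called down and 2 up, and up to 10 unfolded protein genes down and 3 up. The median, the mean and the camera direction differed in sign for NF-kB and chemokine, mitochondrially encoded and ribosomal protein genes.

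**Figure D3:**
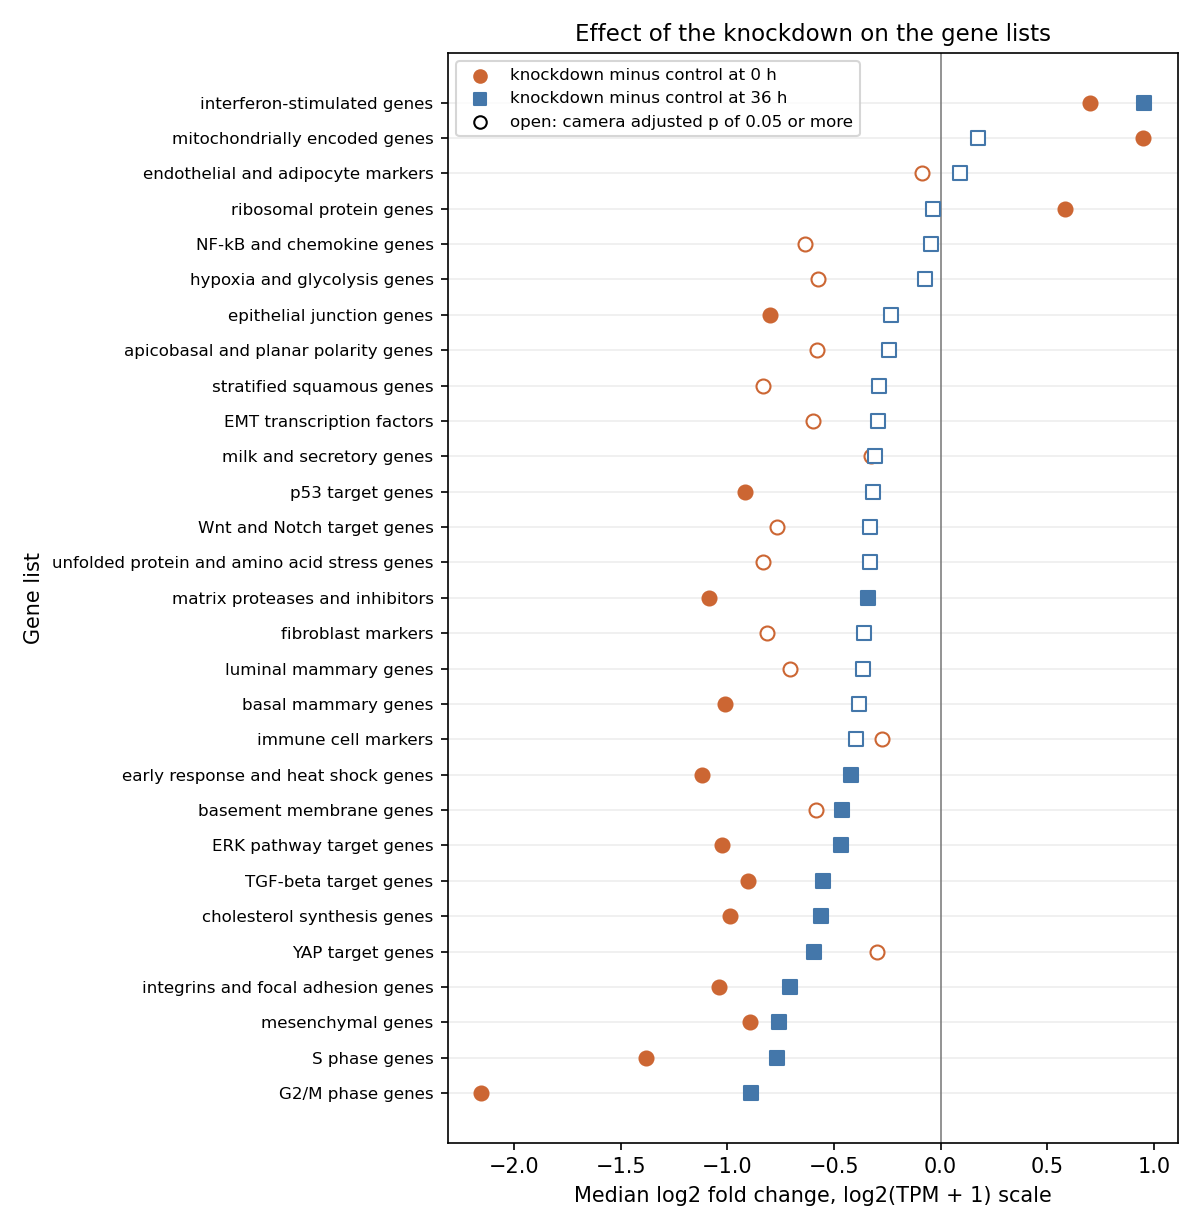
Median log2 fold change of the members of the gene lists described (vertical axis) for the knockdown minus control at 0 h (circles) and 36 h (squares), on the log2(TPM + 1) scale, where filled marks passed camera at the preset correlation. G2/M phase genes stand at -2.15 and -0.89 and interferon-stimulated genes at 0.70 and 0.96, and without scaling none passed with an estimated correlation.

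The knockdown effects at both times were compared across genes. Across genes, which are not independent replicates, the knockdown effects at 0 h and 36 h had r = 0.524 (Spearman correlation 0.543). Of the called genes, 83 were up at both times where 4.0 were expected from the counts and 214 were down at both times where 34.4 were expected, and of 2617 called at either time 2517 had the same sign. Only Krt6a (ENSMUSG00000058354), a stress keratin, was called in opposite directions, -0.80 at 0 h (adjusted p = 0.0185) and 0.93 at 36 h (adjusted p = 0.0325), but the 0 h value was -0.29 with median-of-ratios scaling (adjusted p = 0.307), and the difference of 1.73 had an adjusted p of 0.127.

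**Figure D4:**
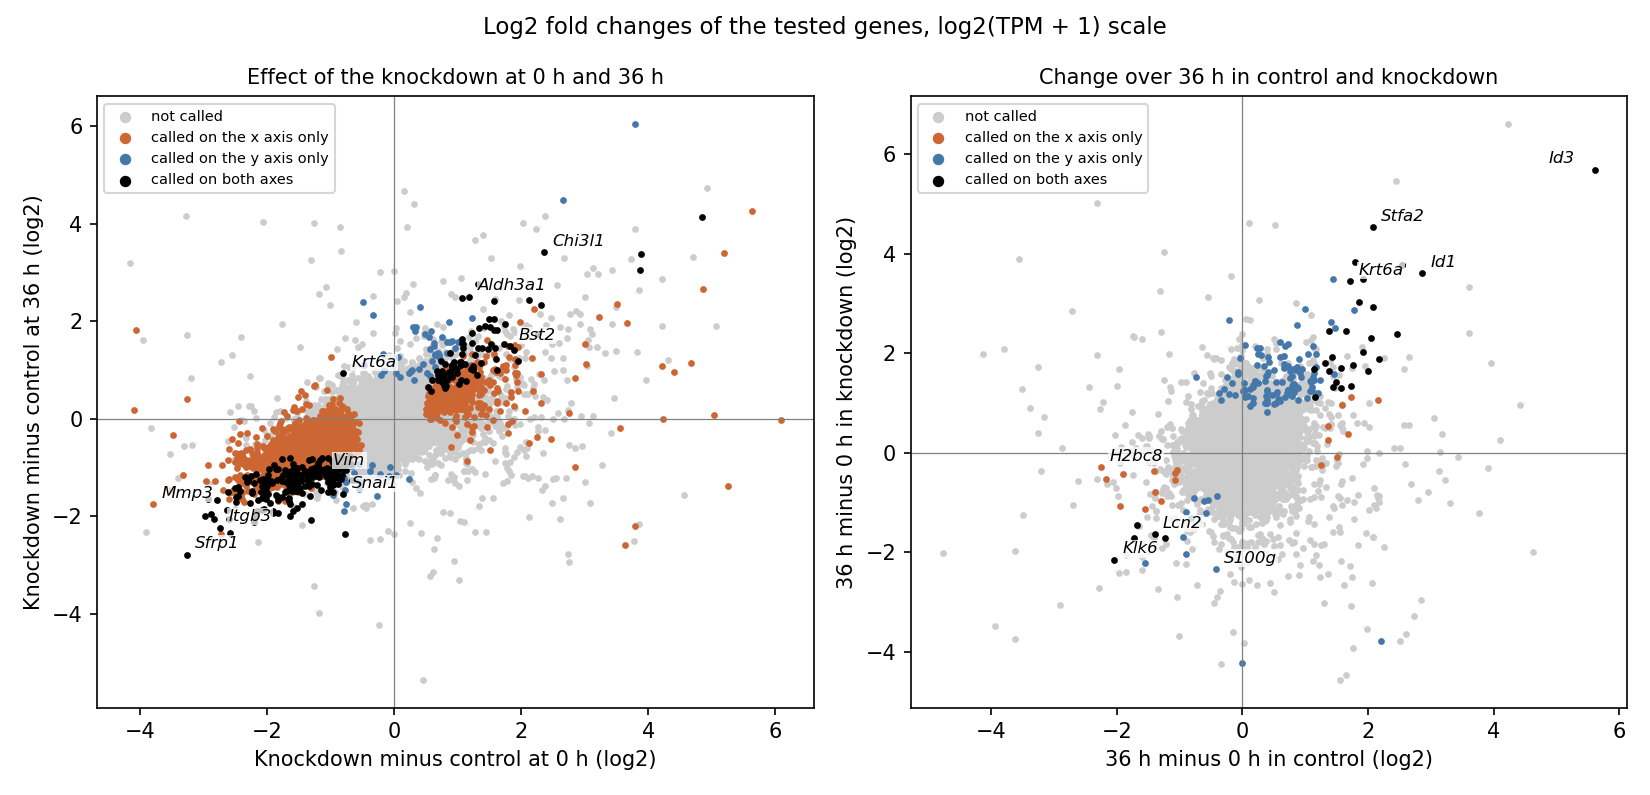
Log2 fold changes of the tested genes on the log2(TPM + 1) scale, left the knockdown at 0 h against the knockdown at 36 h, right the change over 36 h in control against that in the knockdown, colored by which axis they were called on. On the left 83 genes called on both axes are up and 214 down on both, with Krt6a alone in opposite directions, and on the right 28 are up and 5 down on both.

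Over 36 h in control cells Id3 (ENSMUSG00000007872), an inhibitor of helix-loop-helix transcription factors, rose from 4.74 ± 0.569 to 278 ± 15.4 TPM (n = 3 each; 5.61, SE 0.256, adjusted p = 1.79e-06). Its relatives Id1 (2.86, adjusted p = 2.93e-05) and Id2 (1.93, adjusted p = 5.58e-04) rose with it. The stress keratins Krt6a (1.71, SE 0.191, adjusted p = 0.00430) and Krt6b (1.85), the basal keratin Krt5 (1.15), the cystatin-like genes Cstdc5 (2.54) and Cstdc6 (2.55), Cyp2w1 (2.47) and the cornified envelope gene Cnfn (1.73, adjusted p = 0.0571 with median-of-ratios scaling) rose too. The histone genes H2bc8 (-2.25) and H1f2 (-2.17), the protease Klk6 (-2.04), the chemokine Cxcl5 (-1.95) and the iron-binding milk protein Ltf (-1.89) fell. Vim had 0.87 (adjusted p = 0.237), Fn1 -0.61 (adjusted p = 1), Krt14 0.90 (adjusted p = 0.777) and Cdh1 -0.15 (adjusted p = 1), and none passed, although Vim did without knockdown 0 h library 2 (adjusted p = 0.0175). For Vim and Krt14 all 3 libraries at 36 h lay above all 3 at 0 h, with Krt14 at 13390 ± 1035 against 7167 ± 100 TPM.

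In all, 52 genes passed in limma, 36 up and 16 down (69.2% up), and median-of-ratios scaling gave 88, 50 up and 38 down (56.8% up). Without knockdown 0 h library 2 there were 401 genes, 174 up and 227 down, which held all 52. The count was 18, 21 and 18 without control 0 h libraries 1, 2 and 3, 20, 30 and 19 without control 36 h libraries 1, 3 and 4, and 33 without knockdown 36 h library 1. Of the 19 called genes named by rule, 2 kept their call with the replicate block and 7 without control 36 h library 4. In at least 1 fit without 1 library 12 of the 19 lost it, and over all alternatives Ltf lost it in 13 of 25 and H2bc8, Klf2 and Krt5 in 12 of 26 each.

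By gene list, 15 passed camera in control, none of them with an estimated correlation. With median-of-ratios scaling, 6 lists passed with an estimated correlation. With 1 library left out, 0 to 10 cholesterol synthesis genes were called up, and 0 to 8 NF-kB and chemokine genes and 0 to 6 matrix proteases down. NF-kB and chemokine genes had Cxcl5 and Lcn2 (-1.40) down of 23 (8 adjusted over the list alone), a median of -0.43 (camera adjusted p = 2.70e-11, adjusted p = 0.209 with an estimated correlation). Cholesterol synthesis genes had 0 past the limma threshold (3 up adjusted over the list alone), a median of 0.60 (1.78e-12, adjusted p = 0.373 with an estimated correlation). Early response and heat shock genes had Klf2 (-1.55) down of 23 (4 adjusted over the list alone, median -0.48, 1.62e-07, adjusted p = 0.430 with an estimated correlation). Matrix proteases had 0 called (5 down adjusted over the list alone, median -0.28, 1.87e-06, adjusted p = 0.430 with an estimated correlation). ERK targets had 0 called (6 down adjusted over the list alone, median -0.29, 6.33e-06, adjusted p = 0.373 with an estimated correlation). Basal mammary genes had Krt5 up of 19 (2 adjusted over the list alone, median 0.49, 6.81e-06, adjusted p = 0.496 with an estimated correlation). TGF-beta targets had the 3 Id genes up of 21 (4 adjusted over the list alone, median 0.18, 1.73e-04, adjusted p = 0.496 with an estimated correlation). Their median was -0.04 without control 0 h library 3, so no general rise of that list is read from the Id genes. Stratified squamous genes had 4 up and 1 down of 14 (5 and 3 adjusted over the list alone, median 0.34, 0.00370, adjusted p = 0.230 with an estimated correlation). Milk and secretory genes had Lcn2 and Ltf down of 9 (3 adjusted over the list alone, median -0.19, 0.0153, adjusted p = 0.430 with an estimated correlation), but not with median-of-ratios scaling (adjusted p = 0.0842). Immune cell markers had Cd68, a macrophage marker, down of 3 (-1.68; 1 adjusted over the list alone, median -0.31, 0.00313, adjusted p = 0.209 with an estimated correlation).

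Further lists passed camera in control without a called gene, namely mitochondrially encoded genes (median 0.87, 2.41e-05, adjusted p = 0.518 with an estimated correlation), ribosomal protein genes (0.27, 1.01e-05, adjusted p = 0.638 with an estimated correlation), Wnt and Notch target genes (0.17, 0.0114, 3 up adjusted over the list alone, adjusted p = 0.638 with an estimated correlation), basement membrane genes (0.14, 0.0131, adjusted p = 0.584 with an estimated correlation) and S phase genes (0.16, 0.0307, adjusted p = 0.80 with an estimated correlation). S phase genes did not pass without control 0 h library 1 (0.0554) or 2 (0.149) or control 36 h library 1 (0.165), basement membrane genes without control 36 h library 1 (median -0.05, 0.208) or 4 (0.0658), nor Wnt and Notch genes without control 36 h library 1 (0.0569). Leaving out 1 library moved other medians in control as well. Without control 0 h library 1 they were 0.25 for basement membrane genes and -0.79 for immune cell markers, and without library 2 -0.09 for milk genes and -0.52 for immune markers. Without control 0 h library 3 they were -0.04 for TGF-beta targets, -0.93 for immune markers, 0.46 for mitochondrial and 0.14 for ribosomal protein genes. Without control 36 h library 1 they were 0.28 for basal, -0.08 for milk, 0.20 for squamous, -0.47 for protease, 0.08 for TGF-beta target, 0.10 for Wnt and Notch target and 0.09 for S phase genes. Without control 36 h library 3 they were 0.53 for squamous, 0.60 for basement membrane, -0.10 for protease, -0.19 for ERK target, 0.34 for Wnt and Notch target, 0.33 for S phase and 0.58 for mitochondrial genes. Basement membrane genes had 0.05 without control 36 h library 4, and immune markers -0.93 without knockdown 0 h library 2. The other 15 lists did not pass, with medians between -0.11 and 0.31, and median, mean and camera direction differed in sign for p53 target, hypoxia, unfolded protein and fibroblast genes.

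Over 36 h in knockdown cells Id3 rose from 5.12 ± 2.07 to 301 ± 25.4 TPM (n = 3 each; 5.69, SE 0.256, adjusted p = 1.52e-06), and Id1 (3.61) and Id2 (3.49) rose as well. The stress keratins Krt6a (66.2 ± 10.7 to 733 ± 133 TPM, 3.44, SE 0.191, adjusted p = 3.85e-06), Krt6b (3.03) and Krt16 (3.84), the cystatin family genes Stfa2 (4.53), Cstdc5 (3.78) and Cstdc6 (3.77) and the basal keratins Krt5 (1.68) and Krt14 (1.88, adjusted p = 0.0412) rose. Igfbp3 (2.14), the growth factor Nrg1 (1.78), Mcm5 (1.74) and Idi1 of sterol synthesis (2.50) rose too. S100g (-2.34, adjusted p = 0.0442), Klk6 (-2.15), H2ac6 (-1.71), Wfdc17 (-1.71) and Wfdc18 (-1.71) fell. Calls of S100g (adjusted p = 0.0615) and Krt14 (1.48, adjusted p = 0.0567) were lost with median-of-ratios scaling. Vim had 0.88 (adjusted p = 0.106) and Fn1 -0.73 (adjusted p = 0.318), and neither passed, although Vim did without knockdown 0 h library 3 (adjusted p = 0.0482).

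In all, 162 genes passed in limma, 144 up and 18 down (88.9% up), and the median of all genes was 0.33. Median-of-ratios scaling gave 240, 176 up and 64 down (73.3% up). The count was 408, 278 up and 130 down, without knockdown 0 h library 2, which held 157 of the 162, and 1572 without knockdown 0 h library 3. It was 103, 106 and 104 without control 0 h libraries 1, 2 and 3, 100 without control 36 h library 4, and 51, 46 and 57 without knockdown 36 h libraries 1, 2 and 3. Of the 33 called genes named by rule, 9 kept their call with only the groups compared and 14 without knockdown 36 h library 2. In at least 1 fit without 1 library 19 of the 33 lost it, and over all alternatives Ccna2 lost it in 17 of 26, S100g and Krt14 in 16, Perp in 15 and Plk1 in 13.

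By gene list, 11 passed camera in the knockdown, none with an estimated correlation. With median-of-ratios scaling, 2 lists passed with an estimated correlation. With 1 library left out the members called up ranged from 0 to 26 for G2/M, 0 to 12 for S phase, 1 to 12 for basal and 1 to 10 for cholesterol synthesis genes. G2/M phase genes had 4 of 30 up (29 adjusted over the list alone), among them Plk1 (1.59), Cdc25c (1.44) and cyclin A2 (Ccna2, 1.11), a median of 1.11 (camera adjusted p = 7.24e-14, adjusted p = 0.499 with an estimated correlation), and 0.75 with median-of-ratios scaling. Basal mammary genes had 4 of 19 up (11 adjusted over the list alone, median 1.15, 1.85e-06, adjusted p = 0.499 with an estimated correlation). Stratified squamous genes had 4 up and 1 down of 14 (8 and 2 adjusted over the list alone, median 0.79, 0.0117, adjusted p = 0.499 with an estimated correlation). Cholesterol synthesis genes had 3 of 23 up (11 adjusted over the list alone, median 0.96, 1.90e-07, adjusted p = 0.499 with an estimated correlation). S phase genes had Mcm5 up of 32 (7 adjusted over the list alone, median 0.91, 2.08e-04, adjusted p = 0.669 with an estimated correlation). TGF-beta targets had 4 of 21 up (6 adjusted over the list alone, median 0.55, 0.00144, adjusted p = 0.639 with an estimated correlation). Wnt and Notch targets had Lgr6 (1.46) and Hey1 (1.19) up of 16 (5 adjusted over the list alone, median 0.67, 0.00635, adjusted p = 0.669 with an estimated correlation). p53 targets had Perp (1.34), a desmosome protein, up of 20 (3 adjusted over the list alone, median 0.61, 0.0417, adjusted p = 0.931 with an estimated correlation). NF-kB and chemokine genes had Lcn2 (-1.64) down of 23 (5 adjusted over the list alone, median -0.22, 3.36e-06, adjusted p = 0.499 with an estimated correlation). Immune cell markers had Cd68 (-1.46) down of 3 (1 adjusted over the list alone, median -0.59, 0.00702, adjusted p = 0.436 with an estimated correlation). Ribosomal protein genes had 0 of 36 (median -0.33, 6.97e-12, adjusted p = 0.499 with an estimated correlation). The p53 list did not pass without control 36 h library 3 (0.0543), knockdown 0 h library 2 (0.0922) or 3 (0.0526), or knockdown 36 h library 1 (0.0671) or 2 (0.0522). Ribosomal protein genes did not pass without knockdown 0 h library 2 (-0.03, 0.0919), and squamous genes did not pass without knockdown 0 h library 3 (0.210). Immune cell markers had an adjusted p of 0.0596 with median-of-ratios scaling, which also moved the medians of squamous genes to 0.40, TGF-beta targets to 0.18, Wnt and Notch targets to 0.40, NF-kB genes to -0.55, S phase genes to 0.55, cholesterol genes to 0.56, p53 targets to 0.23 and ribosomal protein genes to -0.73. The medians without knockdown 0 h library 2 were 0.69 for basal, 0.31 for TGF-beta target, 0.33 for Wnt and Notch target, -0.49 for NF-kB, 0.44 for S phase, 0.19 for p53 target and 0.53 for cholesterol genes and -0.96 for immune markers. Without library 3 of that group they were 0.90 for TGF-beta targets, -0.12 for NF-kB genes and 0.93 for p53 targets. The other 19 lists did not pass, with medians between -0.37 and 0.70, and median, mean and camera direction differed in sign for 9 of them, among them EMT factors, luminal, milk, protease, ERK, YAP, early response, and endothelial and adipocyte genes.

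The 36 h changes of control and knockdown cells had r = 0.101 across genes (Spearman correlation 0.0618). It was 0.292 without knockdown 0 h library 2, 0.02 without library 1 and 0.053 without library 3 of that group, 0.015 and 0.183 without control 36 h libraries 1 and 3, and 0.066 and 0.159 without control 0 h libraries 1 and 3. Of the called genes 28 rose in both where 0.359 were expected and 5 fell in both where 0.0200 were expected, and 0 went in opposite directions. Of 181 genes called in either, 165 had the same sign, and r among these 181, which were chosen by their calls, was 0.689.

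Whether the knockdown altered the change over 36 h was tested by the difference of the 36 h changes. Every sample at 36 h had been in the migration assay, so this change mixes migration with time in culture. No gene passed in limma (0 at an adjusted p under 0.05, 766 at an unadjusted p under 0.05), and a simulation with 100 genes changed by 2-fold recovered 1% of them. Leaving aside the predicted gene Gm56328 (-4.24), the lowest p-values belonged to Dmkn (1.82), Fgfbp1 (1.70), Id2 (1.57) and Krt6a (1.73), each with an adjusted p of 0.127. Without knockdown 0 h library 2, 10 genes passed, among them Cdc20 (1.37), Aurka (1.16), Id2 (1.53), Krt16 (1.57), Krt6a (1.64) and Ces1f (2.32), chosen after their values were seen. The median of all genes was 0.34, and 0.01 with median-of-ratios scaling. By gene list 7 passed camera, none with an estimated correlation, and the count was 4 without knockdown 0 h library 3. With median-of-ratios scaling, 1 list passed with an estimated correlation. Without knockdown 0 h library 2, 1 list passed camera with an estimated correlation (adjusted p = 0.0373). G2/M phase genes had a median of 1.20 (camera adjusted p = 2.69e-15; 27 of 30 up adjusted over the list alone, adjusted p = 0.822 with an estimated correlation). Proteases had 0.73 (0.00283; 2 up alone, adjusted p = 0.922 with an estimated correlation). ERK targets had 0.62 (0.0211, adjusted p = 0.922 with an estimated correlation). Early response genes had 0.91 (0.0270, adjusted p = 0.922 with an estimated correlation). Squamous genes had 0.59 (0.0415; 4 up alone, adjusted p = 0.799 with an estimated correlation). Mitochondrially encoded genes had -1.08 (4.46e-05, adjusted p = 0.922 with an estimated correlation) and ribosomal protein genes -0.61 (7.45e-20, adjusted p = 0.799 with an estimated correlation). The medians without knockdown 0 h library 2 were 0.37 for proteases, 0.30 for ERK targets, 0.31 for early response genes, 0.30 for squamous genes and -0.33 for ribosomal protein genes. Without library 3 of that group they were 1.14 for proteases and -1.67 for mitochondrial genes, and squamous genes had 0.35 without control 36 h library 3. The mitochondrial median was -0.69 without control 0 h library 3, -0.70 without knockdown 36 h library 2 and -0.04 without knockdown 0 h library 2 (adjusted p = 0.244), and the squamous list did not pass with median-of-ratios scaling (0.28, adjusted p = 0.138), which gave 0.83 for G2/M genes, 0.36 for proteases, 0.31 for ERK targets, 0.50 for early response genes and -1.01 for ribosomal protein genes. ERK targets did not pass without knockdown 0 h library 1 (0.0926) or 3 (0.0651), nor early response genes without knockdown 0 h library 3 (0.103). Squamous genes did not pass either without control 0 h library 2 (0.0663), control 36 h library 1 (0.0649), knockdown 0 h library 1 (0.106) or 3 (0.254), or knockdown 36 h library 1 (0.0520) or 2 (0.0689). The other 23 lists did not pass, and median, mean and camera direction differed in sign for 7 of them, namely EMT factors, mesenchymal, basement membrane, YAP, fibroblast, immune, and endothelial and adipocyte genes.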

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

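The tests of the pattern of counts, of the divergent library and the scale for the G2/M genes, and of the explanations of the interferon-stimulated genes were chosen after the result was seen, while the list tests and the fits without 1 library that they read were planned. 7 gene lists passed the test of the difference between the 36 h changes of knockdown and control cells, each as a median log2 difference. The medians were 0.59 for stratified squamous genes, 0.73 for matrix proteases and inhibitors, 0.62 for ERK pathway target genes, 1.20 for G2/M phase genes, 0.91 for early response and heat shock genes, -1.08 for mitochondrially encoded genes and -0.61 for ribosomal protein genes. Without scaling none of the 7 passed with an estimated correlation. Mitochondrially encoded genes stood at -0.04 without knockdown 0 h library 2 (adjusted p = 0.244). Without that library the medians of squamous, protease, ERK target, early response and ribosomal protein genes were 0.30, 0.37, 0.30, 0.31 and -0.33. In that fit 1 list passed camera with an estimated correlation (adjusted p = 0.0373). G2/M phase genes passed at the preset correlation in each of the 12 fits without 1 library, with a lowest median of 0.81. Among 100 drawn of 200 possible splits of the libraries, 53 gave as many lists (7 in the real split, up to 18 in another), so they do not exclude chance. They are no clean reference for it, because a split that swaps labels at 1 time puts the knockdown effect itself into the difference. For single genes the count says nothing, since all 100 splits reach the 0 of the real split. The highest, 3166, came from swapping control and knockdown at 0 h alone, so the structure it shows is the summed knockdown effect of both times.

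For the other comparisons 3 libraries against 3 make 10 splits, too few for a share under 0.05. Each split other than the real one mixes both groups, so a real difference widens the spread and lowers its count of genes. The counts of genes are therefore no clean reference for chance here either. The knockdown at 0 h had 2550 genes and 1 at most in another split (1 of 10 as large), and 16 lists against 8 (1 of 10). The knockdown at 36 h had 365 genes against 2 (1 of 10) and 13 lists against 15 (2 of 10). The change in control had 52 genes against 2 (1 of 10) and 15 lists against 11 (1 of 10), and that in the knockdown 162 genes against 5 (1 of 10) and 11 lists against 9 (1 of 10).

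About 7 times as many genes passed for the knockdown at 0 h as at 36 h, a ratio of 6.99. Without knockdown 0 h library 2 the ratio was 1.25, because the 36 h count rose from 365 to 2699 while the 0 h count rose from 2550 to 3369, so this library may bear on it through the shared spread. The order turned with only the groups compared (16 against 2176 genes) and with array weights (4684 against 7678). The array weights did not converge, with 32.4 for control 36 h library 4 and 0.027 for knockdown 0 h library 2. Counts with these weights lean on 1 doubted library, so no conclusion on the order is drawn from them. With median-of-ratios scaling the ratio was 3.18, so the scale of the libraries may account for part of it but left it above the 1.5 set for that test. A knockdown effect that is larger at 0 h than at 36 h stays open. Without knockdown 0 h library 2, 10 genes passed the test of the difference, in a fit that recovered 29% of simulated 2-fold differences.

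G2/M phase genes were lower in the knockdown, with 30 of 30 called at 0 h and 6 of 30 at 36 h (21 adjusted over the list alone), and adjusted p = 0.637 and 0.733 with an estimated correlation (0.0101 and 0.0289 with median-of-ratios scaling). With 1 library left out the called members ranged from 29 to 30 at 0 h and from 0 to 28 at 36 h. With only the groups compared, 2 of the 94 genes named by rule at 0 h kept their call. The calls at 0 h therefore depend on fitting all 4 groups together. A divergent library and the scale as the whole cause are argued against by a median of -1.84 at 0 h without knockdown 0 h library 2 and of -0.78 at 36 h with scaling. Of 10000 random lists matched on length and expression, 0 percent had a median as low at 36 h. A candidate explanation is fewer dividing cells in the knockdown, since 149 KEGG cell cycle and DNA replication genes outside the fixed lists had a median of -0.39 at 36 h, against -0.09 for matched random lists. With an estimated correlation their camera p was 0.344, and this remains a hypothesis found and tested on the same libraries.

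Interferon-stimulated genes were higher in the knockdown as a list, with 5 of 30 called at 0 h and 3 of 30 at 36 h (30 of 30 positive). Without scaling the list did not pass with an estimated correlation (adjusted p = 0.637 and 0.733). With median-of-ratios scaling, 3 of the 30 lists passed that test at 0 h and 8 at 36 h. RNA of immune cells was tested by the summed immune cell markers at 36 h. They stood at 5.23 TPM (SD 0.241) in the knockdown and 5.28 TPM (SD 0.599) in control, so the sum was not higher. This sum cannot decide the question, because only 3 markers were measured. Cd68, the most abundant, stood at 2.25 against 3.28 TPM, so its fall can hide a rise of the others. The samples were HC11 cells, an epithelial line, and the design names no source of immune cells. Knockdown 0 h library 2 as the cause is argued against by a median of 1.00 at 0 h without it, but the median was 0.16, with 4 genes called down, without library 3. The control cells carried a control construct, so a response common to both constructs would be present in both groups. A response particular to the knockdown construct cannot be told apart from an effect of lower Snai1, because every knockdown library carries that construct. The median of 0.96 at 36 h is what either could give.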

How the results depend on the processing

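The alternatives with array weights, with both doubted libraries (knockdown 0 h library 2 and control 36 h library 4) left out, and with knockdown 0 h library 2 left out and median-of-ratios scaling were chosen after seeing the data. For the named genes, 4499 of 5411 values kept their side of the threshold (31 of these, uncalled, changed sign), 882 lost their call, 30 gained one and 0 reversed. The depth of the libraries is unknown, so how far it limits low genes such as Snai1 cannot be given. The causes of the moves below were not tested, apart from the fewer samples of some fits.

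Genes changed by the knockdown at 0 h numbered 1258 with no filter, 1011 with the replicate block, 1394 with the block and median-of-ratios scaling, 16 with only the groups compared and 4684 with array weights. At 36 h they numbered 192 with no filter, 856 with median-of-ratios and 933 with quantile scaling, 5 with the block, 33 with the block and scaling, 2176 with only the groups compared, 7678 with array weights, 1448 without both doubted libraries, and 2753 without knockdown 0 h library 2 and with scaling. Over 36 h in control they numbered 88, 111, 6, 4, 247, 4890, 160 and 395 with median-of-ratios scaling, quantile scaling, the block, the block and scaling, only the groups compared, array weights, both libraries out, and knockdown 0 h library 2 out with scaling. In the knockdown they numbered 40 with the block, 51 with the block and scaling, 18 with only the groups compared, 664 with array weights, 258 without both libraries and 409 without knockdown 0 h library 2 and with scaling. Genes whose 36 h change differed numbered 1 with no filter, median-of-ratios scaling, quantile scaling or the block, 90 with array weights, 8 without both libraries and 5 without knockdown 0 h library 2 and with scaling. The array weights did not converge and gave control 36 h library 4 a weight of 32.4, so the counts with them lean on that library.

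Snai1 at 0 h lost its call with no filter (-0.80, adjusted p = 0.131), median-of-ratios (-0.51, 0.191) and quantile scaling (-0.71, 0.0611), the block (-0.80, 0.0724), the block and scaling (-0.51, 0.216) and only the groups compared (-0.80, 0.155). At 36 h it lost it with the block (-1.50, 0.169) and the block and scaling (-1.47, 0.105). The filter of 5 TPM removes Snai1 and gives no value, nor does a fit of only the groups compared for the difference. The labels do not say that replicate numbers pair libraries, and same-number correlations ran from -0.154 to 0.128 at 0 h and were 0.036 and 0.132 at 36 h. With an estimated correlation 0 lists passed in each of the 5 comparisons, from 16, 13, 15, 11 and 7, and with median-of-ratios scaling as well 3, 8, 6, 2 and 1 passed.

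Leaving out 1 library gave 755 to 5869 genes for the knockdown at 0 h, 24 to 2699 at 36 h, 18 to 401 over time in control, 46 to 1572 in the knockdown and 0 to 10 for the difference. Lists ranged over 15 to 18, 11 to 15, 12 to 18, 10 to 12 and 4 to 10. Snai1 ranged from -0.93 to -0.64 at 0 h and from -1.64 to -1.42 at 36 h, and the correlation of the time effects from 0.015 to 0.292.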

Other observations

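The NRF2 test was set up before its values were seen, and the KEGG pathways and the genes named for both times were chosen after seeing the data. In the knockdown at 36 h, 6 of 53 glutathione metabolism genes rose and 0 fell, with a median of 0.28 (camera adjusted p = 2.94e-05; adjusted p = 0.997 with an estimated correlation). Of 36 genes of drug metabolism by cytochrome P450, 4 rose, with a median of 0.41 (adjusted p = 0.997 with an estimated correlation). Of 45 ECM-receptor interaction genes 3 were down (median -0.56) and of 142 focal adhesion genes 7 (median -0.38), each with an adjusted p = 0.997 with an estimated correlation. At 0 h 46 of the 142 were down (median -0.76, adjusted p = 0.997 with an estimated correlation). Of 240 pathways, 65, 49, 5, 10 and 10 passed camera for the knockdown at 0 h and at 36 h, the change in control, the change in the knockdown and their difference, and 0 passed with an estimated correlation.

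Several genes outside the lists were lower in the knockdown at 0 h and at 36 h. The collagen gene Col8a1 had log2 fold changes of -2.21 and -2.11, the sialyltransferase St6gal1 -2.19 and -2.02, the semaphorin receptor Nrp2 -2.07 and -1.87, and the fatty acid synthase Fasn -1.65 and -1.68.

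Gsta1, Aldh3a1 and Ces1f were among the largest rises in the knockdown at 36 h, and higher NRF2 activity was tested as a hypothesis on 22 other target genes. Gsta1 was called up at 0 h as well (2.13, adjusted p = 0.00416), while Ces1f had a difference of the 36 h changes of 2.88 (adjusted p = 0.358). At 36 h 16 of the 22 were positive, 0 passed in limma, and 0.03 percent of 10000 random lists were as high. Their median of 0.248 lay just under the bound of 0.25 set for the test, and the camera p of 2.18e-04 became 0.343 with an estimated correlation, so the test leaves the hypothesis open. At 0 h the median was -0.50, as in random lists (-0.49).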
